A study of Homo sapiens with 46 samples.

How the data were processed

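RNA from nasal epithelial cells of 23 patients with cystic fibrosis was measured on exon arrays, with 1 array before and 1 after treatment for each patient, 46 arrays in all. Digitoxin, a cardiac glycoside that inhibits the sodium-potassium ATPase, was given at 100 µg per day (8 patients) or 50 µg per day (8 patients), and 7 patients received placebo. The labels give the placebo samples a dosage of 100. What this number stands for is not stated, and placebo was set to 0 in the dose trend. Per the labels' protocols, samples were snap-frozen in Trizol, total RNA was purified with QIAzol and RNeasy columns, and biotin-labelled cDNA was hybridised. Per the submitters' processing notes, the arrays were processed with RMA (robust multi-array averaging) and Partek 6.6 on genome build hg19. The deposited values are log2 RMA values per probe set. The log2 scale is not stated in the labels and was taken from the values, which run from 0.886 to 13.5 with array medians between 3.64 and 3.92. The notes state neither filters nor the level of summarisation. Arrays give no counts, so the number of patients limits the precision.

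The deposited table holds 147768 probe sets. An annotation table names genes for 25956 of them, and the other 121812 were not used for genes. Of the annotated probe sets, 21623 map to 1 gene and were kept, and 4333 map to several genes and were left out, which removed KRT5 and MUC5AC, among others. A further 54 probe sets were left out of naming and tests, since they could describe a person. The rule covered Y-linked genes, XIST, TSIX, immune receptor segments and HLA genes outside the fixed lists, and other X-linked genes were kept. For each of 17448 genes the probe set with the highest mean was used, and the 30% of genes with the lowest mean were left out, leaving 12213. No positions are given, since the hg19 annotation was not at hand. The 46 arrays held 0 identical pairs. As a check of the pairing, gene values centred on the group means were correlated between the arrays of each patient: the median over 23 pairs was 0.524 (range 0.199 to 0.769, across genes, which are not independent replicates).

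Changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, residual degrees of freedom 20, prior 4.09), with the patient as a block and a post-minus-pre term for each arm. Differences between arms and the mean of both digitoxin arms against placebo are contrasts of those terms. The linear trend on dose (per 100 µg) came from a separate fit. It held the patient as a block, a post-minus-pre term common to the arms and the slope of the change on dose. Arms were also compared before treatment, on the 23 pre-treatment arrays. P-values were adjusted by Benjamini-Hochberg over 12213 genes with a threshold of 0.05. The design text names pre- and post-treatment samples of each subject and an analysis of variance with a pair of factors that it does not name, so the fit without the replicate block was run beside it: it also put 0 genes past the threshold in each change and difference between arms, with a lowest adjusted p of 0.999 for the 100 µg arm.

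Before the data were examined, 27 gene lists were fixed from textbook knowledge: ciliated, secretory and goblet, basal and squamous epithelial cells; neutrophils, monocytes and macrophages, T and NK cells, B and plasma cells, mast cells and eosinophils, and erythrocytes; NF-κB response, tumour necrosis factor (TNF) receptor signalling, neutrophil chemoattractants, other cytokines and chemokines, interferon-stimulated genes, class II antigen presentation, sodium-potassium ATPase, airway ion transport, endoplasmic reticulum stress, heat shock, hypoxia, immediate early genes, cell cycle, NRF2 antioxidant genes and cholesterol synthesis; ribosomal proteins and mitochondrial respiration. The erythrocyte list kept 1 gene after the filter and was not tested; the other 26 were. No gene is in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 26 lists in each comparison, with camera at an estimated correlation and fry beside it. Because the list calls varied, the mean change of each list per patient was also tested with an exact sign-flip test within arms and an exact permutation of arm labels between arms (two-sided), chosen after the data were seen. The smallest p that sign flips allow is 0.00781 with 8 patients and 0.0156 with 7. Relations between the changes of 6 pairs of lists over the 23 patients, chosen after the data were seen, were tested with 1e+05 permutations.

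Genes are named by a rule set before the data were examined: genes past the threshold first, and where fewer than 5 pass, the 5 of lowest unadjusted p in each direction with an absolute log2 value of at least 0.5, given as not passing. The rule adds, for each list past camera, the 4 members with the largest statistic in its direction, and a set of fixed genes, of which 11 were tested (among those not tested, IL6 was too dim, and MUC5AC and KRT5 had no probe set of their own). Other members are given as examples.

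Alternatives were no replicate block, the patient as a random block, no variance moderation, eBayes with trend and robust settings, array quality weights, a further quantile normalization, median centring, no filter on dim genes, a 50% filter, the mean of a gene's probe sets and leaving out each patient in turn. Each count was also set against up to 100 splits of the samples, the real one included: the order of pre and post was swapped within patients for a change, and arm labels were exchanged between patients for a difference. On simulated data with 200 changed genes among 12213 independent genes, the fit recovered 67.5% of log2 changes of 0.5 in an arm of 8 and 33% of differences of 0.5 between arms. At a log2 size of 1 these were 97.5% and 90.5%, and at 0.25 they were 5.5% and 0%, so small changes would mostly be missed. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.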

Results

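Gene expression was measured in nasal epithelial cells of 23 patients with cystic fibrosis, sampled before and after 100 µg of digitoxin per day (8 patients), 50 µg per day (8 patients) or placebo (7 patients). The median signal of the 46 arrays lay between 3.64 and 3.92 on the log2 scale, and 12213 genes were compared. Values below are log2 differences with the standard error of the limma fit (SE) for genes. Where a list change within an arm carries a spread, it is the standard deviation over patients (SD). List differences between arms carry none here. In limma, 0 genes passed an adjusted p of 0.05 in each comparison, so every gene is given by its value. Between arms, lower and higher refer to the change (post minus pre), not to the level after treatment. Chance gives 611 independent genes at an unadjusted level under 0.05, and the counts below pass this only for the 100 µg change, 100 µg minus placebo and the dose trend. At least 27 of 100 splits of the samples reached each of these 3 counts.

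The first comparison asks what differed after 100 µg of digitoxin per day. Lymphocyte and antigen presentation genes were lower and basal cell and mitochondrial genes higher in list tests with a preset correlation. T and NK cell markers fell by a mean of 0.319 (SD 0.420, n = 8, lower in 6 of 8 patients), and all 10 tested markers were lower, among them CD96 (-0.49 ± 0.12, SE), CD3D (-0.51 ± 0.16) and CD2 (-0.35 ± 0.12). Class II antigen presentation genes, which display peptides to helper T cells, fell by a mean of 0.386 (SD 0.514, lower in 5 of 8), with all 7 members lower, including HLA-DPA1 (-0.60 ± 0.18) and HLA-DRA (-0.50 ± 0.17). The adjusted p with an estimated correlation was 0.119 for both lists. Basal cell markers, of the progenitor layer of the airway epithelium, had a mean of 0.212 (SD 0.226, higher in 7 of 8), with all 10 members higher, including KRT14 (0.76 ± 0.26) and SNAI2 (0.35 ± 0.12). Their adjusted p was 0.377 with an estimated correlation. Basal cell markers were also above 0 at 50 µg (0.106, higher in 5 of 8) and on placebo (0.096, higher in 5 of 7). Their difference between 100 µg and placebo (0.116) did not pass camera with the preset correlation. Adjusted over the list alone, 6 of 7 class II genes, 4 of 10 T and NK cell markers, KRT14 and SNAI2 of the basal list and the T cell chemokine CCL5 (-0.72 ± 0.20) passed, against 0 over all genes. Of the lists that did not pass, HSPB1 of heat shock (0.31 ± 0.09), AKR1C2 of the NRF2 list (1.00 ± 0.27) and P4HA1 of hypoxia (-0.25 ± 0.07) did so too. Here and below, this adjustment was made within each of the 26 lists in each comparison. There was no correction across lists or comparisons, so some members would pass by chance.

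In the same arm, the NF-κB response list had a mean of -0.238 (SD 0.404, lower in 6 of 8) with 17 of 18 genes lower, among them the cytokine IL1B (-0.97 ± 0.51), the cyclooxygenase PTGS2 (-0.86 ± 0.38) and the feedback inhibitor TNFAIP3 (-0.54 ± 0.20). Neutrophil markers stood at -0.430 (SD 0.774, lower in 4 of 8), with MNDA at -0.99 ± 0.43 and FPR1 at -0.82 ± 0.53. Interferon-stimulated genes (-0.267, SD 0.917), immediate early genes (-0.172, SD 0.278), other cytokines (-0.151, SD 0.271), monocyte and macrophage markers (-0.141, SD 0.439), B and plasma cell markers (-0.133, SD 0.427) and ciliated cell markers (-0.103, SD 0.380) were also lower than other genes. All 23 tested mitochondrial respiration genes were higher, with a mean of 0.171 (SD 0.284), including NDUFB7 (0.33 ± 0.12), CYC1 (0.31 ± 0.10) and COX8A (0.29 ± 0.10), and ribosomal protein genes had a mean of 0.111 (SD 0.191). These 10 lists passed camera with the preset correlation, with adjusted p between 0.299 and 0.574 with an estimated correlation. For all 13 lists that passed, the mean was smaller than its SD. Without 1 patient of the arm, the call was lost for the B cell (0.00), basal (0.15), interferon (-0.01), monocyte (-0.05) and ribosomal (0.06) lists, and the ciliated list turned to 0.02. The call stayed, with a smaller mean, for the neutrophil (-0.25), NF-κB (-0.15), immediate early (-0.10), cytokine (-0.09) and mitochondrial (0.09) lists. For other patients left out, the interferon list went to -0.45 and the monocyte list to -0.22.

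The 13 other lists did not pass in the 100 µg arm. Means below 0 were -0.142 for neutrophil chemoattractants, -0.049 for mast cells and eosinophils, -0.027 for airway ion transport, -0.022 for cholesterol synthesis, -0.019 for TNF receptor signalling, -0.016 for secretory and goblet cells, -0.014 for hypoxia and -0.010 for endoplasmic reticulum stress. Means above 0 were 0.008 for heat shock, 0.047 for squamous cells, 0.054 for the sodium-potassium ATPase, 0.064 for NRF2 antioxidant genes and 0.133 for the cell cycle. Among the fixed genes, the neutrophil chemoattractant CXCL8 stood at -0.85 ± 0.48, CFTR, the chloride channel mutated in cystic fibrosis, at -0.73 ± 0.43. TNF was at -0.24 ± 0.16, ICAM1 at -0.30 ± 0.23, NFKBIA at -0.12 ± 0.12 and the TNF receptor adaptor TRADD at 0.13 ± 0.10. The ATPase subunit ATP1B1 was at -0.14 ± 0.12, the secretory cell product SCGB1A1 at 0.24 ± 0.25 and the ciliated cell regulator FOXJ1 at -0.15 ± 0.15.

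**Figure D1:**
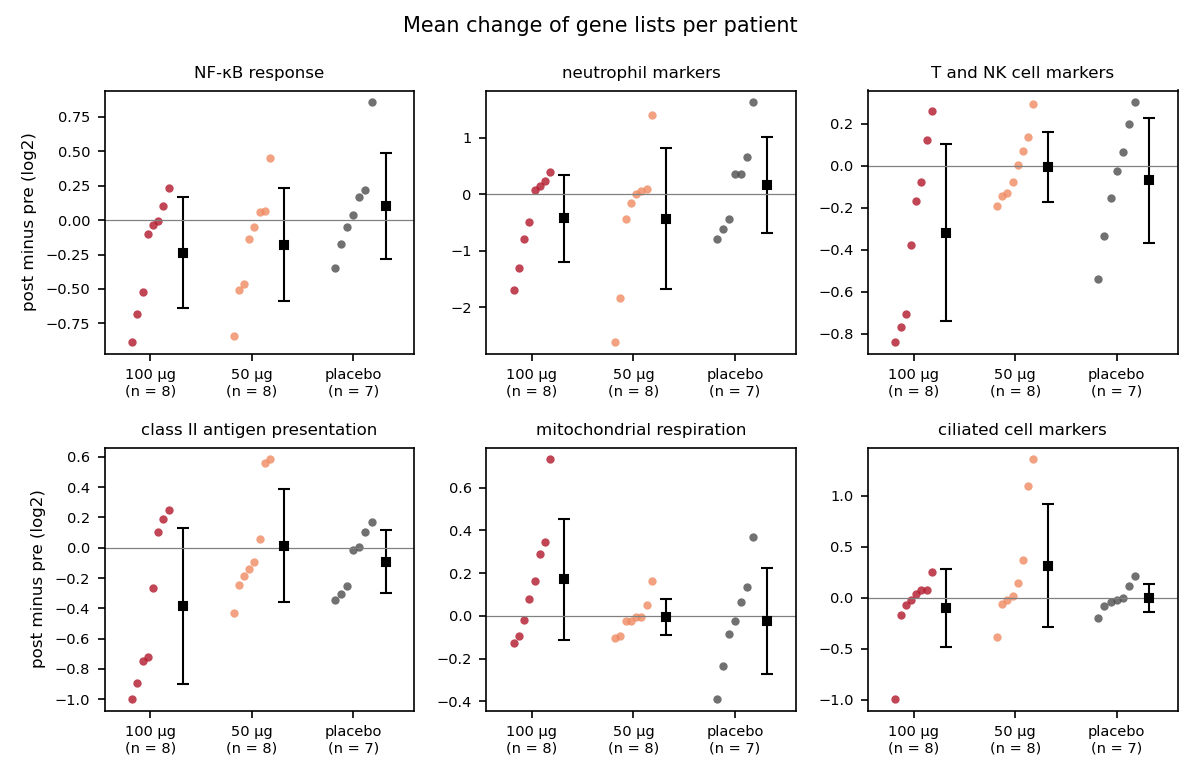
Mean log2 change (post minus pre) of 6 gene lists in each patient of the 3 arms (points), with the arm mean and SD (squares and bars). T and NK cell markers and class II genes had arm means of -0.319 and -0.386 at 100 µg and -0.006 and 0.012 at 50 µg, and the patients of each arm overlap those of the others.

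Of single genes in the 100 µg arm, TCN1, a vitamin B12 binding protein of secretory granules, was higher in 8 of 8 patients (0.67 ± 0.13, 1.59-fold, adjusted p = 0.239). The SMN complex member GEMIN7, singled out after its values were seen since it falls short of the size the rule asks for in this arm, was also higher in 8 of 8 (0.42 ± 0.07) and had the lowest adjusted p of the comparison (0.0616). SCAI (0.53 ± 0.12), ANKRD6 (0.70 ± 0.19), the aldo-keto reductase AKR1C2 (1.00 ± 0.27) and the ubiquitin ligase RNF181 (0.54 ± 0.15) completed the higher genes. FGL2, a fibrinogen-like protein of activated leukocytes (-0.60 ± 0.13), the nuclear pore protein POM121 (-0.81 ± 0.18) and the zinc finger gene ZNF91 (-0.95 ± 0.23) were lower in 8 of 8 patients, followed by the leukocyte genes CD48 (-0.79 ± 0.19) and DOCK10 (-0.55 ± 0.13). limma put 0 genes past the threshold and 961 at an unadjusted level under 0.05 (710 higher, 251 lower). The median change over all tested genes was 0.0398 in this arm, against -0.0062 on placebo. Camera compares a list with the other genes, so this shift enters its calls. GEMIN7 passed without variance moderation, after a further quantile normalization and with 50% of genes left out. Without 1 patient of the arm, GEMIN7 (0.44), CD55 (-0.75) and ZDHHC12 (0.47) passed.

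After 50 µg per day, ciliated cell markers were higher, with all 20 tested above 0 and a mean of 0.312 (SD 0.604, n = 8, higher in 5 of 8 patients). The highest patients stood at 1.35 and 1.09, the next at 0.370 and the lowest at -0.386. RSPH4A (0.60 ± 0.25) and RSPH1 (0.52 ± 0.25), of the ciliary radial spokes, and HYDIN (0.54 ± 0.23), of the central pair apparatus, were among them. Squamous cell markers had a mean of 0.241 (SD 0.886), with KRT13 at 0.62 ± 0.33. Neutrophil markers (-0.436, SD 1.25, lower in 4 of 8), interferon-stimulated genes (-0.226, SD 0.292, lower in 6 of 8), immediate early genes (-0.185, SD 0.449) and the NF-κB response list (-0.177, SD 0.409) were lower. For neutrophil markers the lowest patients stood at -2.61 and -1.84 and the next at -0.447. The adjusted p was 0.692 for each of these 6 lists with an estimated correlation, and 0 of their members passed when adjusted over the list alone or over all genes. Without 1 patient of the arm, the call was lost for the neutrophil (-0.13), NF-κB (-0.08), immediate early (-0.08) and squamous (0.13) lists, and the ciliated list fell to 0.16 with the call kept. For other patients left out, the squamous list went to 0.52, the neutrophil list to -0.70 and the NF-κB list to -0.27.

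The genes of lowest p in the 50 µg arm included ZNF578 (0.89 ± 0.19, higher in 7 of 8), SPECC1 (0.65 ± 0.14, higher in 8 of 8), the cornified layer genes KRT1 (0.66 ± 0.17) and SPRR2G (1.06 ± 0.31) and the hormone gene STC1 (0.52 ± 0.17). EPB41, of the membrane skeleton (-0.79 ± 0.20), the small GTPase RIT1 (-0.62 ± 0.21), SLED1 (-0.50 ± 0.18), the folate enzyme MTHFD2 (-0.72 ± 0.26) and the ATP synthase subunit ATP5F1E (-0.79 ± 0.32) were lower. CXCL8 was at -0.58 ± 0.48, IL1B at -0.69 ± 0.51, TNFAIP3 at -0.28 ± 0.20, CFTR at 0.39 ± 0.43 and FOXJ1 at 0.37 ± 0.15. limma put 0 genes past the threshold (lowest adjusted p 0.776) and 375 at an unadjusted level under 0.05 (233 higher, 142 lower), the latter between 267 and 605 with each patient left out in turn.

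In the placebo arm, which gives the background of the same visits without the drug, squamous cell markers were higher (mean 0.312, SD 0.433, n = 7, higher in 5 of 7), with 14 of 14 above 0, including CNFN (0.69 ± 0.40) and KRT4 (0.47 ± 0.25). Immediate early genes had a mean of 0.160 (SD 0.401). Interferon-stimulated genes (-0.253, SD 0.759) and cholesterol synthesis genes (-0.125, SD 0.366) were lower, with IFI44L at -0.81 ± 0.54 and MSMO1 at -0.32 ± 0.13. Their adjusted p with an estimated correlation was 0.851 to 0.971, and 0 members passed when adjusted over the list alone. Neutrophil markers (0.158, SD 0.854) and the NF-κB response list (0.101, SD 0.386) did not pass. Without 1 patient of the arm, the call was lost for the cholesterol (-0.01), immediate early (0.03) and interferon (-0.02) lists, and the interferon list then ranked above other genes. For other patients left out, the interferon list went to -0.42 and the cholesterol list to -0.20.

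Single genes in the placebo arm included the transcribed pseudogene TMEM14EP, higher in 7 of 7 patients (0.71 ± 0.14, adjusted p = 0.275), the G protein subunit GNAI3, also higher in 7 of 7 (0.71 ± 0.24), SVIL (0.58 ± 0.18), IFRD1 (0.95 ± 0.32) and PRDM15 (0.79 ± 0.27). POM121 was lower in 7 of 7 (-0.98 ± 0.19, adjusted p = 0.275), as was the histone gene H4C4 (-0.63 ± 0.20), followed by H4C2 (-0.56 ± 0.21), MGC34796 (-0.54 ± 0.17) and LOC100287704 (-0.51 ± 0.17). limma put 0 genes past the threshold and 300 at an unadjusted level under 0.05 (129 higher, 171 lower), the latter between 249 and 479 with each patient left out in turn.

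**Figure D2:**
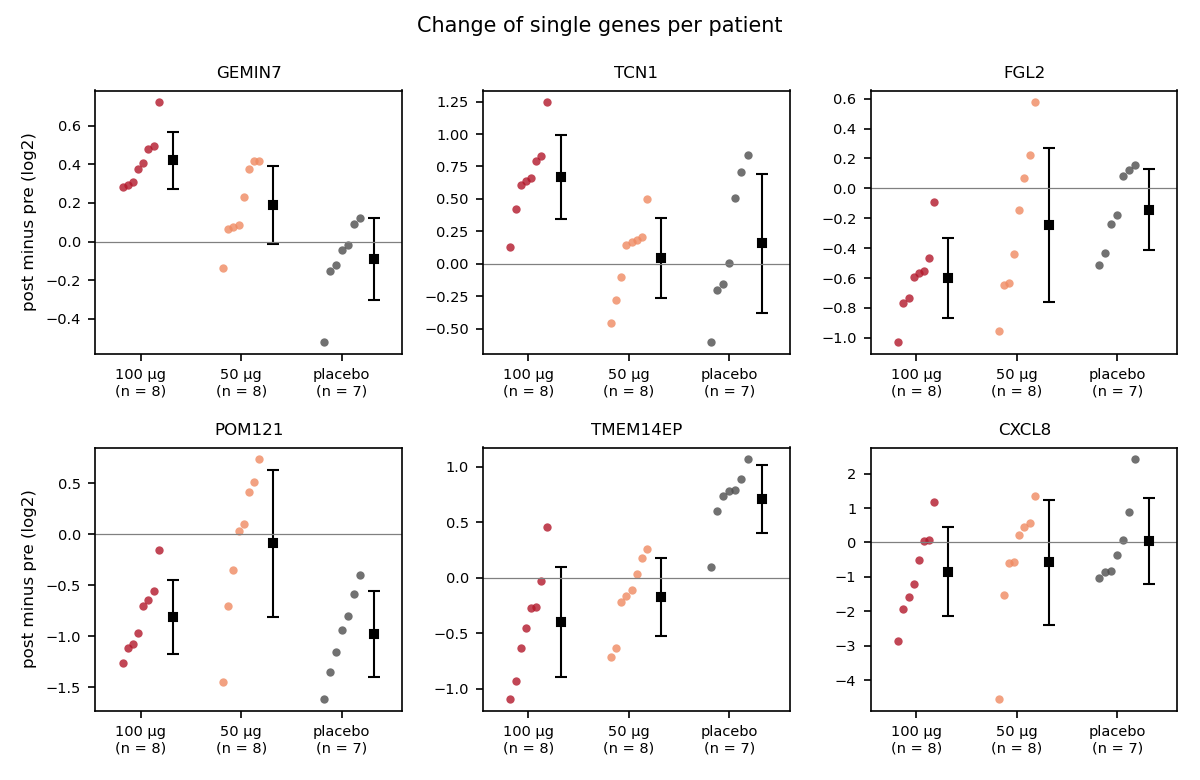
Log2 change (post minus pre) of 6 genes in each patient of the 3 arms (points), with the arm mean and SD (squares and bars). GEMIN7 and TCN1 lie above 0 in 8 of 8 patients at 100 µg, POM121 lies below 0 in 8 of 8 patients at 100 µg and 7 of 7 on placebo, and TMEM14EP lies above 0 in 7 of 7 on placebo.

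The next comparison asks whether the change after 100 µg differed from that on placebo. The change was lower than on placebo, by differences of -0.339 for the NF-κB response list (17 of 18 genes lower), -0.588 for neutrophil markers (11 of 12) and -0.332 for immediate early genes (13 of 15). Genes of these lists moved together, with estimated correlations of 0.467, 0.718 and 0.470, so gene counts are not counts of replicates. The exact permutation p over patients was 0.1225, 0.1866 and 0.0769 in the same order. Other cytokines and chemokines differed by -0.184, T and NK cell markers by -0.249 and class II genes by -0.294 (7 of 7). Neutrophil chemoattractants (-0.176), monocytes and macrophages (-0.076), TNF receptor signalling (-0.058) and interferon-stimulated genes (-0.014) did not pass. PTGS2 (-1.40 ± 0.55), IL1B (-1.37 ± 0.74), FOS (-1.05 ± 0.39) and CXCR4 (-0.80 ± 0.41) were among the members. The class II gene HLA-DPB1 (-0.46 ± 0.16) was the 1 member of these lists to pass when adjusted over the list alone. AKR1C2 (1.28 ± 0.40) and ATP1B3 (0.60 ± 0.19) did so in lists that did not pass. Squamous markers (-0.264) were also lower, and mitochondrial respiration (0.194, 23 of 23 higher) and ribosomal protein genes (0.119) higher. The adjusted p of the 9 lists was 0.375 to 0.750 with an estimated correlation, and the exact permutation of arm labels gave a lowest p of 0.0769 (immediate early genes), adjusted to 0.697. Without 1 patient, the call was lost for the ribosomal (0.07) and squamous (-0.14) lists. The call stayed, with a smaller difference, for the neutrophil (-0.34), NF-κB (-0.21), immediate early (-0.20), cytokine (-0.12) and mitochondrial (0.11) lists.

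Among genes, TMEM14EP had a lower change after 100 µg than on placebo (-1.11 ± 0.20, 2.16-fold lower, adjusted p = 0.0908, lower in 7 of 8 treated patients). IFRD1 (-1.51 ± 0.44), the coenzyme Q gene COQ8A (-0.84 ± 0.25), UBXN2B (-1.57 ± 0.48) and the leukocyte signalling gene HCLS1 (-0.54 ± 0.17) were lower too. GEMIN7 (0.51 ± 0.11), SVIP (0.52 ± 0.13), H4C4 (1.02 ± 0.27), TNFAIP1 (0.50 ± 0.14, higher in 8 of 8 treated patients) and SRP9 (0.56 ± 0.15), of the signal recognition particle, were higher. CXCL8 differed by -0.89 ± 0.70, TNFAIP3 by -0.69 ± 0.29, CFTR by -0.45 ± 0.62 and TRADD by 0.11 ± 0.14. limma put 0 genes past the threshold and 678 at an unadjusted level under 0.05 (466 higher, 212 lower), with a median difference over all tested genes of 0.0475. TMEM14EP passed with array quality weights (-1.23) and when either of 2 patients was left out (-1.23 and -1.22).

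For the change after 50 µg minus that on placebo, ciliated cell markers were higher (0.316, 19 of 20), led by HYDIN (0.61 ± 0.34) and RSPH4A (0.57 ± 0.37). So were secretory and goblet cell markers (0.245, 10 of 15), led by TFF3 (0.94 ± 0.34) and BPIFB1 (0.87 ± 0.35), and cholesterol synthesis genes (0.218, 9 of 10). The secretory list changed by 0.112 at 50 µg and by -0.133 on placebo, and its level after treatment was 7.48 against 7.50. Neutrophil markers (-0.594, 12 of 12 lower), immediate early genes (-0.345, 13 of 15) and the NF-κB response list (-0.279, 16 of 18) were lower. Neutrophil markers started at 6.208 at 50 µg against 5.777 on placebo and ended at 5.771 against 5.935. After treatment, immediate early genes stood at 6.004 against 6.151 and the NF-κB response list at 6.046 against 6.231. With an estimated correlation the adjusted p of these 6 lists was 0.782, and 0 members passed when adjusted over the list alone. NUP85, a nuclear pore gene (0.72 ± 0.18), SPECC1 (0.81 ± 0.21), the taste receptor gene TAS2R41 (0.88 ± 0.23), ZNF578 (0.99 ± 0.28) and POM121 (0.89 ± 0.26) were higher. TMEM14EP (-0.88 ± 0.20), RAB33B (-0.50 ± 0.13), GNAI3 (-1.19 ± 0.32), PCDHB18P (-0.57 ± 0.16) and the ubiquitin ligase PELI1 (-0.60 ± 0.18) were lower. limma put 0 genes past the threshold (lowest adjusted p 1.00) and 417 at an unadjusted level under 0.05 (208 higher, 209 lower). Without 1 patient, the call was lost for the neutrophil (-0.28), NF-κB (-0.15), cholesterol (0.10) and secretory (0.14) lists. The ciliated list fell to 0.17 and the immediate early list shrank to -0.21, with the call kept. Ciliated changes at 50 µg were largest in patients at 1.35 and 1.09, with the next at 0.370.

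The changes at the 2 doses were compared with each other. In the labels, the patient numbers at 50 µg lie before and after those at 100 µg, mostly before, and placebo numbers lie among both. Whether the numbers follow the order of enrolment is not stated. If they do, dose cannot be fully told apart from time, here or in the dose trend. Ciliated cell markers had a lower change after 100 µg than after 50 µg (-0.415, 19 of 20 lower), with RSPH1 at -0.94 ± 0.35 and DNAH5, a dynein arm gene, at -0.86 ± 0.38. Class II genes (-0.398, 7 of 7), T and NK cell markers (-0.313, 9 of 10) and B and plasma cell markers (-0.165, 6 of 7) had a lower change as well, and mitochondrial respiration genes a higher one (0.176, 21 of 23). After treatment, the levels of class II (6.44 against 6.36), T and NK cell (4.87 against 4.61) and B and plasma cell lists (4.82 against 4.63) were higher at 100 µg, as they were before it. CD96 (-0.53 ± 0.17) and CD2 (-0.52 ± 0.17) passed when adjusted over the list alone, as did CHAC1 of endoplasmic reticulum stress (0.42 ± 0.13) and P4HA1 of hypoxia (-0.34 ± 0.10), whose lists did not pass. Over all genes 0 passed. The adjusted p of the 5 lists was 0.261 to 0.610 with an estimated correlation. TCN1 (0.62 ± 0.19), RIT1 (0.97 ± 0.30), H2AC25 (0.56 ± 0.19), TOLLIP-DT (0.86 ± 0.25) and UST-AS1 (0.74 ± 0.22) had a higher change after 100 µg. ZNF578 (-1.17 ± 0.27), ZNF91 (-1.33 ± 0.33), PLCB4 (-0.51 ± 0.17) and CXorf22 (-0.81 ± 0.26) were lower. limma gave 0 genes past the threshold and 388 at an unadjusted level under 0.05 (237 higher, 151 lower). Without 1 patient, the call was lost for the B cell (-0.03) and mitochondrial (0.10) lists, and the ciliated list shrank to -0.27 with the call kept. The largest ciliated changes at 50 µg were 1.35 and 1.09, with the next at 0.370, against a highest of 0.255 at 100 µg.

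The mean change of both digitoxin arms was set against the change on placebo. Immediate early genes, induced within minutes of a stimulus, were lower (-0.338, 14 of 15), and FOS (-1.01 ± 0.34), DUSP1 (-0.72 ± 0.26) and EGR1 (-0.62 ± 0.22) passed when adjusted over the list alone, with 0 over all genes. Neutrophil markers (-0.591, 11 of 12), the NF-κB response list (-0.309, 17 of 18), squamous markers (-0.167) and other cytokines (-0.138) had a lower change and mitochondrial respiration genes a higher one (0.106). Squamous markers had mean changes of 0.047 at 100 µg and 0.241 at 50 µg against 0.312 on placebo, and the list did not pass in the 100 µg arm or for 50 µg minus placebo. The adjusted p of the 6 lists was 0.684 to 0.822 with an estimated correlation, and the lowest p of the exact permutation was 0.0587 (immediate early genes), adjusted to 0.817. TMEM14EP had the lowest adjusted p of the genes (0.0646, 2.00-fold lower). HCLS1 (-0.54 ± 0.15), PELI1 (-0.58 ± 0.16), COQ8A (-0.74 ± 0.22) and IVNS1ABP (-0.76 ± 0.22) were lower. NUP85 (0.62 ± 0.15), TAS2R41 (0.72 ± 0.20), TAS2R38 (0.58 ± 0.17), H4C4 (0.82 ± 0.24) and SPECC1 (0.58 ± 0.18) were higher. limma put 0 genes past the threshold and 591 at an unadjusted level under 0.05 (333 higher, 258 lower). TMEM14EP passed with array quality weights (-1.07), with 50% of genes left out and when either of 2 patients was left out (-1.10 and -1.06). Without 1 patient, the call was lost for the mitochondrial (0.05), cytokine (-0.08) and squamous (-0.03) lists. The neutrophil (-0.35), NF-κB (-0.18) and immediate early (-0.21) lists kept the call with a smaller difference. For other patients left out, the mitochondrial list went to 0.17 and the squamous list to -0.29. The linear trend on dose gave 0 genes past the threshold in limma (lowest adjusted p 0.169) and 697 at an unadjusted level under 0.05 (495 higher, 202 lower).

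NF-κB response genes went with neutrophil markers in the same patients. Over the 23 patients, the change of the NF-κB response list and that of the neutrophil list had a Pearson r of 0.908 and a Spearman rho of 0.864 (permutation p = 1e-05 for each, the smallest the permutations can give, adjusted to 1.5e-05 and 3e-05 over 6 relations). Within the arms r was 0.884, 0.949 and 0.913 (100 µg, 50 µg, placebo), and it was 0.907 without the 2 patients farthest from the median neutrophil change. Neutrophil changes had the same kind of relation to immediate early genes (r = 0.864, rho = 0.774, permutation p = 1e-05 and 4e-05, adjusted 1.5e-05 and 6e-05) and to other cytokines and chemokines (r = 0.842, rho = 0.800, permutation p = 1e-05 for each, adjusted 1.5e-05 and 3e-05). These were 0.828 and 0.848 without the 2 farthest patients, 0.863, 0.862 and 0.855 within the arms for immediate early genes, and 0.775, 0.916 and 0.918 for cytokines. Class II genes went with T and NK cell markers (r = 0.795, rho = 0.772, permutation p = 2e-05 and 3e-05, adjusted 2.4e-05 and 6e-05, r = 0.693 without the 2 farthest), with r of 0.898, 0.332 and 0.921 within the arms.

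**Figure D3:**
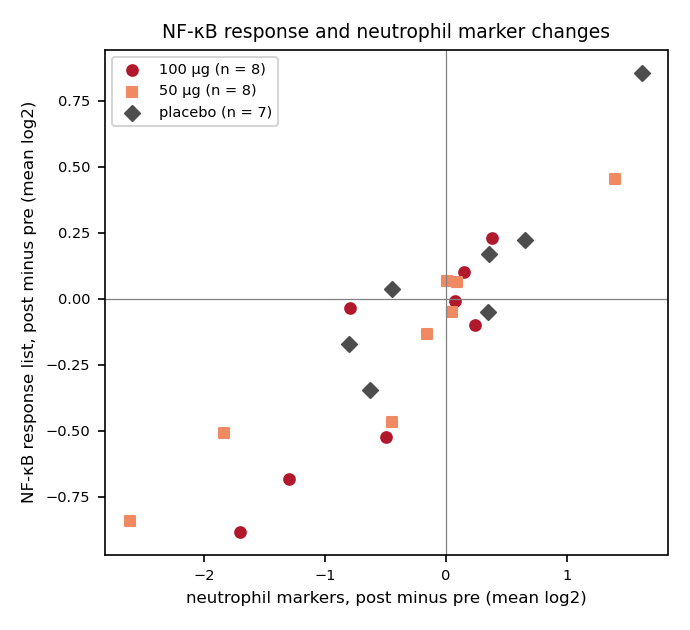
Mean log2 change of the NF-κB response list (y axis) against that of neutrophil markers (x axis), 1 point per patient, by arm (8, 8 and 7 patients). The points follow a rising line in each arm (r = 0.884, 0.949 and 0.913), and the arms overlap.

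The mean changes of the arms were hardly alike over all genes, which are not independent replicates. Over genes, r was 0.190 (rho 0.168) between 100 µg and 50 µg, -0.044 (rho -0.047) between 100 µg and placebo and -0.086 (rho -0.056) between 50 µg and placebo. With the sign of each patient's change redrawn, 15, 82 and 48 of 100 draws, the real signs included, were as far from 0.

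Before treatment, limma put 0 genes past the threshold between either digitoxin arm and placebo, with 364 genes (100 µg) and 271 genes (50 µg) at an unadjusted level under 0.05. With each patient left out in turn these counts ran from 213 to 868 and from 161 to 394. The 50 µg arm started with lower T and NK cell markers than placebo (-0.480, 10 of 10 lower, adjusted p = 0.106 with an estimated correlation, exact permutation p = 0.0138, adjusted to 0.360). Of the 10, 8, including CD2 (-0.79 ± 0.21) and GZMA (-0.76 ± 0.22), passed when adjusted over the list alone. Class II genes were lower as well (-0.409, 7 of 7, adjusted p = 0.148 with an estimated correlation), with HLA-DOA (-0.56 ± 0.17) past the threshold adjusted over the list alone. Squamous (0.661), neutrophil (0.431), basal (0.200) and immediate early (0.198) lists were higher and interferon-stimulated (-0.330), secretory (-0.268) and monocyte (-0.250) lists lower in that arm, with adjusted p of 0.590 to 0.819 with an estimated correlation. The 100 µg arm started with lower cholesterol synthesis (-0.311), secretory (-0.264), NRF2 antioxidant (-0.243) and mitochondrial respiration (-0.088) lists and higher B cell (0.238) and cell cycle (0.172) lists than placebo (adjusted p of 0.566 to 0.920 with an estimated correlation). AHNAK2 (1.09 ± 0.30) and the extracellular matrix gene TNC (0.59 ± 0.19) were higher and ORMDL3 (-0.52 ± 0.14) lower in the 50 µg arm. SETD1B (1.19 ± 0.41) was higher and UBE2N (-0.79 ± 0.24) lower in the 100 µg arm.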

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

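The tests that take neutrophil and T and NK cell changes into account were chosen after the results were seen; the others in this part were planned.

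A patient far from the others of the arm stood out in 9 of 141 sets of changes, against 7.1 that chance gives. The gap to the nearest patient, as a share of the range, was 0.656 for ciliated markers and 0.637 for SCAI in the 100 µg arm. In the 50 µg arm it was 0.700 for mast cell and eosinophil markers, 0.559 for squamous markers, 0.583 for SPRR2G and 0.530 for EPB41. On placebo it was 0.682 for airway ion transport, 0.603 for mast cells and eosinophils and 0.583 for GNAI3.

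Lists that differed between arms in camera with the preset correlation, and in no other list test, are given as mean log2 differences. For 100 µg minus placebo these were class II -0.294, immediate early -0.332, mitochondrial respiration 0.194, neutrophils -0.588, NF-κB response -0.339, other cytokines -0.184, ribosomal proteins 0.119, squamous -0.264 and T and NK cells -0.249. For 50 µg minus placebo they were cholesterol synthesis 0.218, ciliated 0.316, immediate early -0.345, neutrophils -0.594, NF-κB response -0.279 and secretory 0.245. Between 100 and 50 µg they were class II -0.398, B and plasma cells -0.165, ciliated -0.415, mitochondrial respiration 0.176 and T and NK cells -0.313. For both doses minus placebo they were immediate early -0.338, mitochondrial respiration 0.106, neutrophils -0.591, NF-κB response -0.309, other cytokines -0.138 and squamous -0.167.

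Chance was not excluded for any count of genes at an unadjusted level under 0.05. As many genes as the real split came from 27 of 100 splits for the 100 µg change (961 real, 2989 highest other), 55 of 100 for 50 µg (375, 1073), and 53 of 64 for placebo (300, 2542). For differences it was 38 of 100 for 100 µg minus placebo (678, 4313), 51 for 50 µg minus placebo (417, 2059), 59 for 100 minus 50 µg (388, 2114), 34 for both doses minus placebo (591, 3241) and 28 for the dose trend (697, 3055). It was 48 and 68 for the pre-treatment comparisons of 100 and 50 µg with placebo (364, 4395 and 271, 2311). Lists past camera gave the same answer: 19 of 100 splits for 100 µg (13 lists real, 18 highest other), 42 for 50 µg (6, 10), and 48 of 64 for placebo (4, 11). For differences it was 23 of 100 for 100 µg minus placebo (9, 16), 61 for 50 µg minus placebo (6, 11), 69 for 100 minus 50 µg (5, 15) and 48 for both doses minus placebo (6, 13). Some splits gave several times the real count of genes, which points to a structure of the samples or to genes that vary together; the 2 were not told apart. For 100 µg minus placebo, 1 split put 2112 genes past the adjusted threshold.

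The change of the NF-κB response list was lower after 100 µg than on placebo (difference -0.339 ± 0.207, SE over patients, and -0.21 without 1 patient), and a change in the neutrophil content of the samples, which may account for part of it, cannot be told apart from an effect of the arm. With the change in neutrophil markers (without S100A8 and S100A9, which epithelium also expresses) as a covariate, the difference was -0.105 ± 0.094, or -1.11 standard errors, and the slope on neutrophils 0.333 ± 0.036. The same holds for unequal starting values: with the pre-treatment value as a covariate the difference was -0.279 ± 0.187 (-1.50 standard errors), and the unadjusted difference is itself under 2 standard errors. The neutrophil genes of highest signal, S100A9 (mean log2 10.1) and S100A8 (6.74), were at 0.24 ± 0.29 and 0.04 ± 0.22 in the 100 µg arm, which says little on neutrophil content, since epithelium expresses them too. An effect of digitoxin on NF-κB response genes in the epithelium, on neutrophil entry, or neither stays open.

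Class II genes were lower in the 100 µg arm (-0.386 ± 0.139). With the pre-treatment value as a covariate the change stayed at -0.333 ± 0.116 (-2.88 standard errors). This was past the bound set beforehand against high starting values of the arm as the cause. The slope on the starting value was -0.755 ± 0.234. The covariate was centred on the placebo mean, and the arm started at 6.827 against 6.757 on placebo, so the fit had little to move. High starting values are therefore not settled as a cause. These standard errors pool the arms, and the 100 µg arm had the widest spread (SD 0.514, against 0.372 at 50 µg and 0.208 on placebo). Its own exact sign-flip test gave p = 0.0938, adjusted to 0.519. A loss of T and NK cells, or of the cells that come with them, is a candidate explanation: with the change in their markers as a covariate, the change was -0.085 ± 0.112 (-0.754 standard errors), with a slope of 0.944 ± 0.191. The markers of highest signal, NKG7 (mean log2 6.19) and CD8A (5.41), were at -0.27 ± 0.19 and -0.02 ± 0.08; signal differs between probe sets and does not rank transcripts. Whether digitoxin caused such a loss was not tested beyond the comparison with placebo.

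Mitochondrial respiration genes were higher in the 100 µg arm (0.171, SD 0.284, and 0.09 without 1 patient of the arm). A further quantile normalization left 116% of the change (0.198), above the bound set beforehand for a shift in the arrays' overall signal distribution. RMA as a rule includes this step, so a repeat could remove little, and such a shift is not settled. A rise in the relative signal of all bright genes could not be told apart: the 1209 other genes of highest signal had a median change of 0.054, or 31.4% of it, between the bounds set beforehand. The 100 µg arm started below placebo for this list (6.814 against 6.902) and ended above it (6.985 against 6.879). Unequal starting values were not tested as a cause here. An effect of digitoxin on mitochondrial genes stays open as a hypothesis, with a change smaller than the spread between patients.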

How the results depend on the processing

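The exact tests, median centring of the lists, the further settings of the dose trend and of named genes and the fits without the patient of lowest array weight were chosen after the data were seen; the other settings were planned. Gene counts stayed at 0 in the settings run, with these exceptions. In the 100 µg change 1 gene (GEMIN7) passed without variance moderation, 1 after a further quantile normalization and 1 with 50% of genes left out. TMEM14EP, 1 gene, passed with array quality weights in 100 µg minus placebo, both doses minus placebo and the dose trend, and with 50% left out in both doses minus placebo. Leaving out each patient in turn gave 0 to 3 genes for the 100 µg change and 0 to 1 for 100 µg minus placebo, both doses minus placebo and the trend. Counts at an unadjusted level under 0.05 moved more: 67 to 307 over the changes and differences without the replicate block, and up to 605 for 50 µg, 479 for placebo and 868 for the 100 µg arm before treatment with 1 patient left out. With fewer genes tested the adjustment is milder; otherwise the cause was not tested.

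List calls depended on the test: camera with an estimated correlation gave 0 lists in each of the 9 comparisons, as did fry and the exact tests, which also ask another question (any change, not a difference from other genes). Array quality weights gave 5 lists for 100 µg, 2 for placebo, 4 for 100 µg minus placebo, 3 for 50 µg minus placebo, 3 for both doses minus placebo and 3 for the 100 µg arm before treatment. A further quantile normalization gave 8 for 100 minus 50 µg and 3 for the 100 µg arm before treatment, and median centring 8 for 100 minus 50 µg. Leaving out each patient in turn gave 2 to 7 lists for 50 µg, 1 to 7 for placebo, 3 to 6 for 50 µg minus placebo, 4 to 10 for 100 minus 50 µg, 3 to 10 for both doses minus placebo, and 4 to 11 and 4 to 12 before treatment for 100 and 50 µg. Without the patient of lowest array weight placebo had 1 list. The ciliated list in the 100 µg arm ran from -0.154 to 0.024 and the interferon list on placebo from -0.419 to -0.021 over the patients left out; at the upper ends they ranked above other genes. Without the placebo patient of lowest array weight the latter was -0.021. Of 49 lists called in the 7 comparisons of changes, with the 15 before treatment not followed list by list, 28 lost the call with array quality weights and 5 without the replicate block, in the same direction. The B and plasma cell list in the 100 µg arm had a mean of 0.05 with 50% of genes left out. The cause was not tested. Signal was low for 8 of the 10 T and NK cell genes, with mean levels of 4.31 to 4.83 against array medians of 3.64 to 3.92, and higher for CD8A (5.41) and NKG7 (6.19).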

Other observations

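The components and relations in this part were chosen after the data were seen. The component with the largest share of variance (38.45%) had ciliary genes such as RSPH4A, TEKT1, DNAH6 and RFX3 at its high end, and squamous and inflammatory genes such as SPRR3, RPTN, CNFN, S100A9, IL1B and FPR1 at its low end. Over the samples this component had r of 0.95 with the ciliated list and -0.80 with the squamous list. Its r was 0.88 with the mast cell and eosinophil list, of 4 tested genes, and 0.76 with the secretory list. It had r of -0.91 with the sodium-potassium ATPase, -0.83 with immediate early, -0.75 with NF-κB response and -0.71 with neutrophil lists. The third component (7.02%) had IL1B, FPR1, AQP9, MNDA, TREM1, CXCL8 and PTGS2 together at its high end. Over the samples it had r of 0.55 with the neutrophil list, -0.65 with ribosomal proteins and -0.59 with mitochondrial respiration. The second (13.58%) had r of -0.70 with the B and plasma cell list and 0.67 with the NRF2 list. The squamous genes SPINK7, SPRR3 and RPTN were at its high end with ELF2, HNRNPH1 and EZH2, and SETD1B, ZNF774, GSTT1 and MUC7 at its low end.

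Changes of ribosomal protein and mitochondrial respiration genes went together over the 23 patients (r = 0.822, rho = 0.670, permutation p = 1e-05 and 8e-04, adjusted 1.5e-05 and 0.00096 over 6 relations). The r was 0.656 without the 2 farthest patients and 0.844, 0.422 and 0.948 within the 100 µg, 50 µg and placebo arms. Squamous and ciliated marker changes were opposed (r = -0.470, permutation p = 0.0350, adjusted 0.0350, rho = -0.209, permutation p = 0.337), but this rests on the 2 farthest patients, without whom r was -0.114, and within the arms it was -0.179, -0.805 and 0.337.

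POM121 was lower in 8 of 8 patients at 100 µg and 7 of 7 on placebo but lower in 3 of 8 at 50 µg (-0.81 ± 0.18, -0.98 ± 0.19 and -0.09 ± 0.18), and it passed in no arm (lowest adjusted p 0.256 in limma). Of the 88301 probe sets not assigned to a single gene that were bright enough to test, 0 passed in any of 7 comparisons, with 5023 at an unadjusted level under 0.05 in the 100 µg change and a lowest adjusted p of 0.342.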
